A study of Mus musculus with 6 samples.

How the data were processed

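Bulk RNA-seq was measured in 6 libraries of wild-type mouse haematopoietic cells, 3 of fresh common myeloid progenitors (CMP) and 3 of expanded CMP. Per the labels' protocols, fresh CMP were taken straight from bone marrow. Expanded CMP were collected from haematopoietic stem cells cultured for 7 days in a serum-free Ham medium with polyvinyl alcohol, thrombopoietin at 100 ng/mL, stem cell factor at 10 ng/mL and an insulin, transferrin and selenium supplement. For each library 10000 cells were sorted into Trizol, cDNA was made with a SMARTer kit, and paired reads of 36 nt were sequenced on an Illumina NextSeq, per the labels' protocols. The antibodies and gates of the sort are not given in the sources used here. All 6 libraries carry the same batch label, so no batch could be compared within.

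The deposited table gives a whole-number count per gene symbol and library. The submitters' processing notes name the genome build mm10, while the aligner, the counting tool, the annotation and the use of strand are not given in the sources used here. The name of the deposited table says that its counts were quantile normalized, but the values do not show it: totals run from 3641949 to 7777072, the largest count from 22664 to 56455, and the number of features at 0 from 32395 to 34914, whereas quantile normalization gives every column the same distribution. The values were therefore treated as unnormalized counts. The design set before the data were examined named limma on log values as the main test and a quasi-likelihood count test if the values were whole-number counts, and the count test was used. Limma after quantile normalization was added as an alternative. If a step before deposit did rescale the counts, the depth and counting errors given here would not hold exactly.

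Of 49585 features, 28896 were at 0 in every library, and 10990 with a mean count of at least 10 over the 6 libraries were tested. Totals were 3641949, 3860858 and 3865201 counts in fresh replicates 1 to 3 and 7777072, 5506902 and 5437390 in expanded replicates 1 to 3, so the expanded libraries were deeper. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with trimmed mean of M-values (TMM) factors, a prior count of 1 and Benjamini-Hochberg adjustment over the tested genes at 0.05. It had no covariates. Fold changes are log2 of expanded over fresh, with a standard error (SE) from the quasi-likelihood variance. The prior count pulls them toward 0 where a group has few counts. Abundances are CPM, the counts scaled to a common library size with TMM factors, as mean ± SD. Where all libraries of a group were at 0, a fold is a lower bound against a floor of 3 counts over the group. Where a group had 1 to 3 counts in all, the ratio of CPM is given with an exact binomial 95% interval. Reads carry no molecular identifiers, so intervals and floors cover counting error only.

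The labels call the replicates of each group biological but name no animals or cultures, so p-values measure the spread between these samples, which may be partly technical. That spread was small. The common coefficient of variation beyond counting noise was 3.16%, and the chi-square per degree of freedom between replicates, over features with at least 20 summed counts, ran from 1.27 to 2.75. All replicate pairs differed by more than sampling noise, and none was merged. Changes far below 1.5-fold could pass the test as a result.

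The 32 gene lists were written before the data were examined, from textbook markers and pathways, as was the rule for named genes. The lists were tested with camera (limma 3.58.1, preset correlation 0.01, at least 3 tested members, adjusted over the 32 lists) and again with an estimated correlation. Members were also counted with the edgeR p adjusted over the list alone. The rule named the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean count of at least 50, groups that did not overlap and no predicted or clone symbol. It also named up to 4 called members of each list by size of change, or up to 2 abundant members where none was called. It added Kit, Cd34, Ly6a, Fcgr3, Fcgr2b, Mpl, Cd48, Slamf1, Flt3, Gata1, Gata2, Spi1 and Cebpa whatever their values. Of the 142 genes it gave, 141 were tested and 137 were called, 136 of these with groups that did not overlap (all but Fcgr2b). Members that are named because they were the few that went against their list were chosen after their values were seen. Itgam and Ahsp were not analysed here.

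Coordinates come from GENCODE M21 on GRCm38, the assembly that mm10 names, matched by symbol, and 47147 of 49585 features matched. Of the named genes, 36 have an exon that overlaps an exon of another gene, and without a stated use of strand such reads cannot be told apart. Near-identical genes (haemoglobin, histone, Hspa1a and Hspa1b, metallothionein, ribosomal protein genes with their pseudogenes) are uncertain where the counting split shared reads. Lars2, Gm26917 and Rn18s-rs5, features prone to ribosomal RNA reads, took 0.995% to 1.70% of counts.

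The scripts were tested on simulated counts for the expanded against fresh comparison. In the step over 10988 genes, the test recovered 58% of genes changed 1.25-fold, 82% at 1.5-fold, 96% at 2-fold and 100% at 4-fold. It called 9 of 10772 unchanged genes, which made up 4.79% of its calls. Few genes were changed (46 to 50 tested per fold), and all genes shared the same dispersion. In the real data 55.8% of tested genes were called, a setting that the simulation did not cover. Camera, run with limma on the simulated counts, picked out a raised list and did not pick out an unchanged one.

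The alternatives planned before the data were examined were prior counts of 0.1 and 10, no filter or a mean count of at least 50, median-of-ratios scaling, scaling to ribosomal protein genes, no abundance trend, a robust prior, a replicate block, each replicate left out, and an estimated correlation for the lists. The prior counts stand for the planned pseudocounts, and the edgeR priors for the planned limma priors. Added after seeing the data were DESeq2 1.42.0, limma on quantile-normalized log2 counts, library totals alone, thinning of every library to 3641949 counts, offsets for GC content and transcript length (known for 97.8% of tested genes), and leaving out Lars2, Gm26917 and Rn18s-rs5. Tables and figures were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.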

Results

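Transcripts of fresh common myeloid progenitors (CMP), the bone marrow cells from which granulocytes, monocytes, red cells and platelets descend, were compared with those of expanded CMP grown from haematopoietic stem cells. The series concerns early recovery driven by progenitors in the spleen, and the comparison asks how progenitors expanded in culture for 7 days differ from their counterparts in marrow. Each group had 3 libraries. The table held 3641949 to 3865201 counts per fresh library and 5437390 to 7777072 per expanded library. Log2 CPM of the tested genes correlated at 0.987 to 0.993 between libraries of a group and at 0.892 to 0.895 between groups, and the first principal component, with 88.2% of the variance, separated the groups. On the second component (3.78%) fresh replicate 1 lay at 19.6, apart from fresh replicates 2 and 3 at -12.8 and -6.98.

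Expanded CMP had less RNA of immediate early, granule, monocyte and red cell genes than fresh CMP (list medians of log2 fold change from -4.95 to -1.72) and more RNA of cholesterol, fatty acid, glycolysis and mitosis genes (0.72 to 1.81). The edgeR quasi-likelihood test called 6128 of 10990 tested genes at an adjusted p under 0.05, 3054 higher and 3074 lower in expanded CMP. Most changes were small: the median fold of called genes was 1.38, 3645 changed by less than 1.5-fold, and 679 rose and 650 fell at least 2-fold. The groups did not overlap for 6582 genes, 59.9% of those tested, where chance gives 10%. Higher calls made up 49.8% of all calls with TMM scaling. With libraries scaled to ribosomal protein genes, which moved the median log2 fold change of all genes to -0.143, they made up 30.1%, with 1972 higher and 4589 lower.

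The largest rises were in Scd1, the stearoyl-CoA desaturase that makes monounsaturated fatty acids (19:44394455-44407879, minus strand, GRCm38), and Trib3, a pseudokinase of the amino acid stress response (2:152337422-152344032, minus strand). Scd1 went from 0.342 ± 0.592 CPM in fresh to 283 ± 6.68 CPM in expanded CMP (SD, n = 3; log2 fold change 9.01 ± 0.72 SE, edgeR adjusted p = 2.43e-44). Trib3 went from 0.342 ± 0.592 to 157 ± 1.93 CPM (8.16 ± 0.73 SE, edgeR adjusted p = 1.97e-39). Each rests on 4 fresh counts, all in fresh replicate 2. Without that library fresh CMP had no counts of either gene. The log2 fold changes of 10.53 and 9.68 then depend on the prior count and are not measured folds. Those of 9.01 and 8.16 are also pulled toward 0 by the prior count, as with other genes that have few counts in a group. Enah, an actin regulator (1:181896384-182019990, minus strand), rose from 1.14 ± 0.443 to 245 ± 5.47 CPM. Nov, a secreted matricellular protein, had no fresh count and 412 expanded counts, so that it was at least 84.8-fold higher (56.0-fold without fresh replicate 2 or 3). Akr1c12, Slc7a11, Chac1 and Aldh1l2 rose by 6.26, 6.02, 6.02 and 5.60 on the log2 scale (Aldh1l2 by 6.57 without fresh replicate 3). Arx and Serpinb2 had 1 fresh count each, and their CPM ratios of expanded to fresh were 316 (95% counting interval 56.5 to 12510) and 186 (33.1 to 7367). The counts lay in fresh replicates 1 and 2, without which Arx and Serpinb2 were at least 71.6-fold and 40.9-fold higher. With any 1 library left out, every CPM ratio given for a gene, or the bound that replaced it, stayed within its interval. This is a weak check, since the intervals are wide and a bound is not an estimate. Exons of Serpinb2 and Aldh1l2 overlap other genes.

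The largest falls included Elane, the neutrophil elastase gene (10:79886247-79888215, plus strand), at 1177 fresh and 3 expanded counts, a CPM ratio of fresh to expanded of 635 (217 to 3085). Dntt, the terminal transferase of early lymphoid cells, had a ratio of 652 (180 to 5390), and the alpha globin gene Hba-a2 one of 499 (88.8 to 19760). Fos (12:85473890-85477273, plus strand) fell from 1279 ± 13.02 to 12.3 ± 3.21 CPM (log2 fold change -6.69 ± 0.096 SE, edgeR adjusted p = 1.29e-56). Its relative Fosb (7:19302696-19310051, minus strand) fell from 437 ± 25.9 to 2.89 ± 0.576 CPM. The heat shock gene Hspa1b, and Tifab, Dnah8, Mpeg1 and Chdh, had log2 fold changes of -7.10, -6.56, -6.18, -5.79 and -7.31. Exons of Chdh overlap Cacna1d, and exons of Dnah8 overlap uncharacterised genes.

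**Figure D1:**
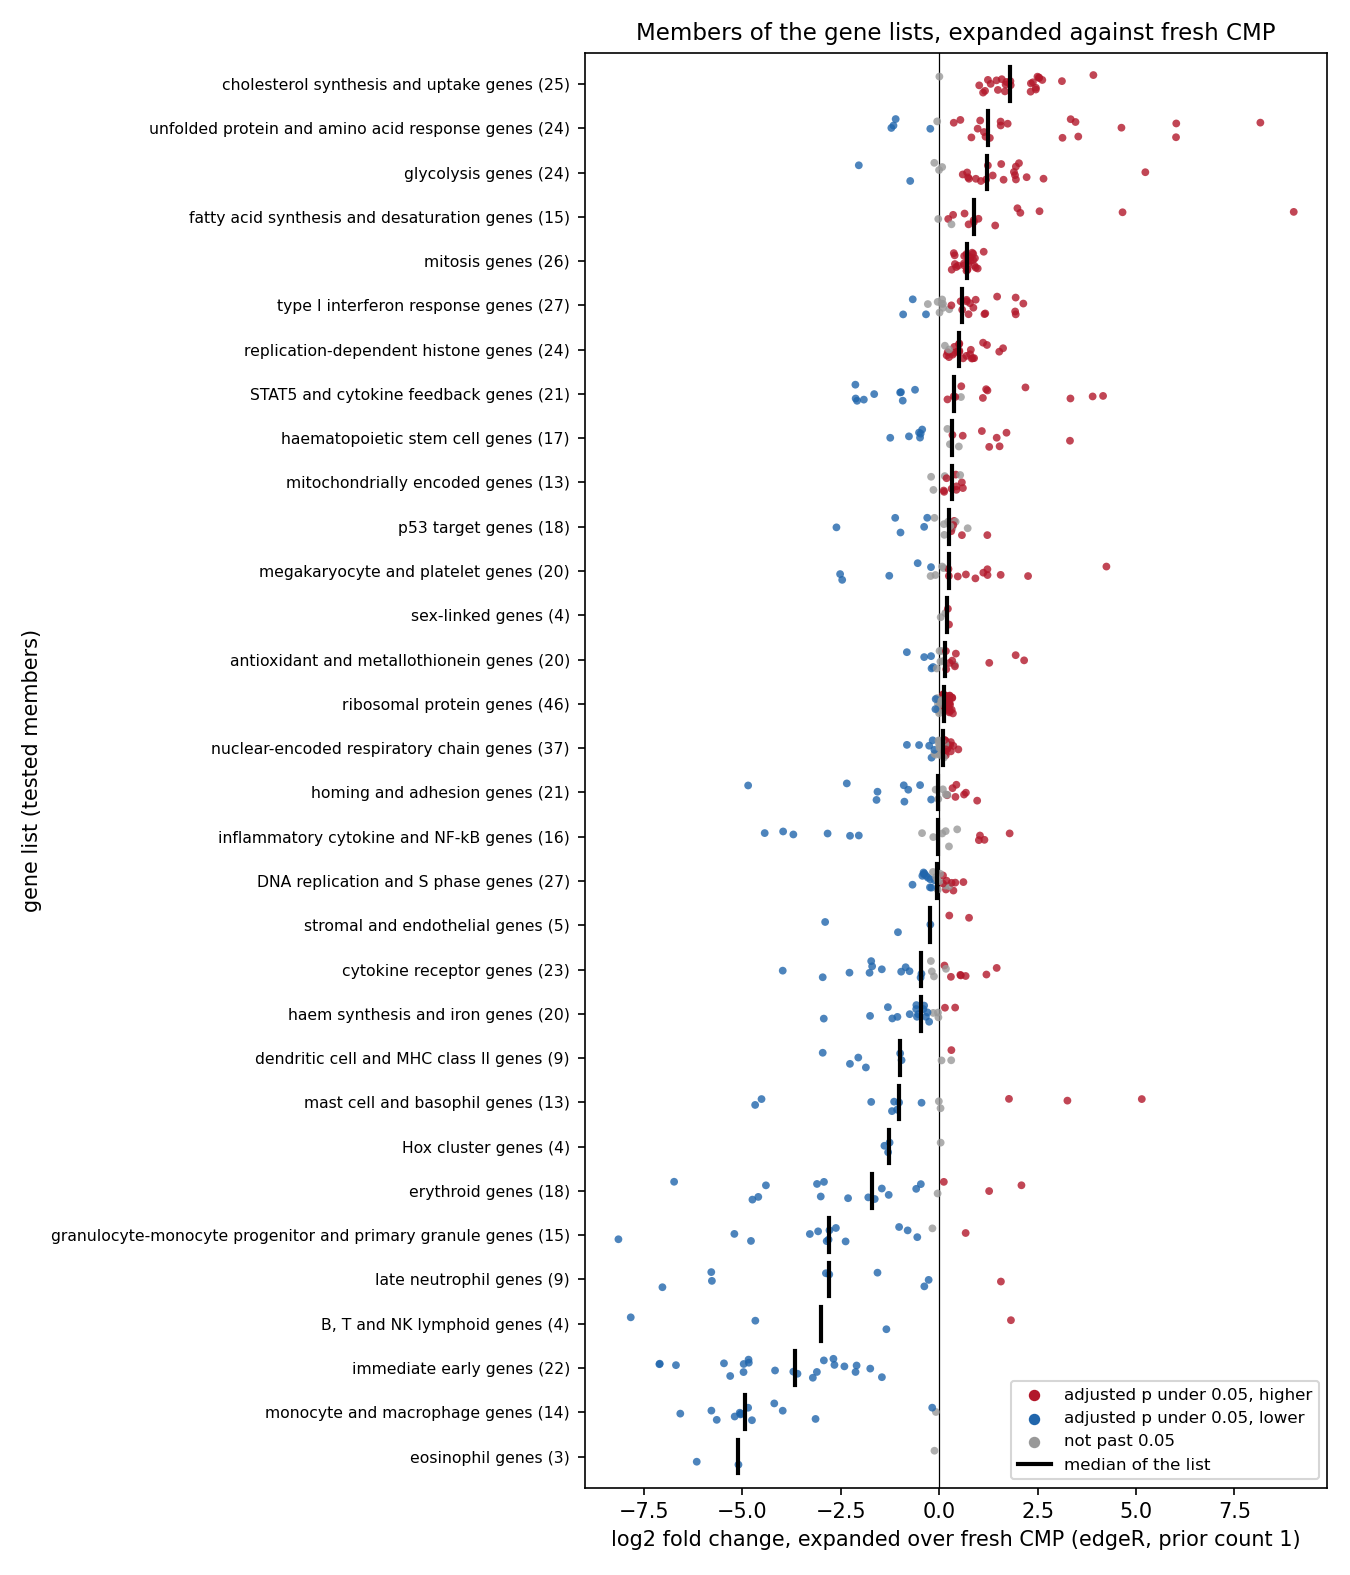
Log2 fold change (expanded over fresh CMP, horizontal axis) of every tested member of the 32 gene lists (rows, with the number of tested members). Each point is a gene, red or blue where its edgeR adjusted p was under 0.05, grey otherwise, and the black bar is the median of the list, from -5.10 for 3 eosinophil genes to 1.81 for 25 cholesterol genes. The median of the ribosomal protein genes was 0.13 as plotted and -0.012 with libraries scaled to those genes, and the medians of the respiratory chain and antioxidant lists changed sign with that scaling too.

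Of the 32 lists, camera called 19, 9 higher and 10 lower in expanded CMP. With an estimated correlation 8 calls held, those of the primary granule, monocyte, erythroid, mitosis, glycolysis, cholesterol, fatty acid and immediate early lists. Among lists that lost their call, the estimate exceeded the preset 0.01 for histone (0.354), mitochondrially encoded (0.35), unfolded protein (0.135) and ribosomal protein genes (0.042). For the others it lay below 0.01, from -0.053 for lymphoid to 0.005 for interferon genes. Those losses therefore do not show that members move together. Counts adjusted over the list alone were the same as those over all genes except where given.

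All 22 immediate early genes, which cells switch on within minutes of a stimulus, were lower in expanded CMP (median log2 fold change -3.66, camera adjusted p = 1.12e-28, 0.00734 with an estimated correlation, 22 lower adjusted over the list alone). Besides Fos and Fosb they included Hspa1b, which fell from 56.8 ± 6.75 to 0.209 ± 0.044 CPM, and Hspa1a, with a CPM ratio of fresh to expanded of 125 (33.9 to 1039). These 2 heat shock genes are near-identical and may share reads. Among 16 inflammatory cytokine and NF-kB genes 6 fell and 4 rose, and the list was not called (camera adjusted p = 0.101; 7 fell and 3 rose with libraries scaled to ribosomal protein genes and with thinned libraries). Tnfaip3, a feedback inhibitor of NF-kB, fell from 636 ± 7.51 to 48.5 ± 3.54 CPM, and the chemokine genes Ccl4, Ccl3 and Cxcl2 had log2 fold changes of -4.44 (-5.06 without expanded replicate 3), -3.97 and -2.84. The 4 that rose were Relb, Tnf, Ccl5 and Nfkb2 (1.79, 1.15, 1.03 and 1.01), and the Ccl5 call was lost without fresh replicate 3 and with ribosomal protein scaling, DESeq2 and GC and length offsets.

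Of 15 genes of granulocyte-monocyte progenitors and primary granules, 13 were lower and 1, Csf3r (0.67), was higher (median -2.79, camera adjusted p = 8.3e-10, 0.0405 with an estimated correlation). Plac8 fell from 534 ± 5.31 to 19.2 ± 1.11 CPM, and Hp and Ms4a3 had log2 fold changes of -5.21 (-4.59 without expanded replicate 1) and -3.29. Of 14 monocyte and macrophage genes 13 were lower and none higher (median -4.95, camera adjusted p = 2.41e-12, 0.0122 with an estimated correlation). Csf1r, the receptor for macrophage colony-stimulating factor, fell from 63.3 ± 2.67 to 4.03 ± 1.49 CPM. Ly6c2 was at least 61.0-fold lower (35.7-fold without expanded replicate 1), Ly86 had a CPM ratio of fresh to expanded of 447 (79.5 to 17710), and Ctss had a log2 fold change of -5.20. The member that did not pass was Cd68 at -0.085. Of 9 late neutrophil genes 8 were lower and 1, Padi4 (1.57), was higher (median -2.79, camera adjusted p = 0.00132). The camera adjusted p was 0.0672 with an estimated correlation and 0.936 with a mean count of at least 50. The largest falls were in genes rare in fresh CMP, while Anxa1 was at -0.27 and lost its call with thinning. S100a9, among the most abundant transcripts of neutrophils, was at 26.0 ± 3.57 CPM in fresh CMP and at 0 in expanded CMP, at least 161-fold lower (94.2-fold without expanded replicate 1). S100a8 and Ngp were at 13.9 ± 0.428 and 16.7 ± 4.12 CPM in fresh CMP, and Ltf at 13.5 ± 3.13.

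Of 9 dendritic cell and MHC class II genes 6 were lower and 1, Bst2 (0.31), was higher (median -0.99, camera adjusted p = 0.0114, but adjusted p = 0.0945 with an estimated correlation). The Bst2 call was lost with ribosomal protein scaling, DESeq2, thinning, GC and length offsets and each replicate left out but expanded replicate 1. Flt3, a receptor of early lymphoid and dendritic progenitors, fell from 142 ± 3.58 to 18.2 ± 0.490 CPM, and H2-DMb1, H2-DMa and H2-Ab1 had log2 fold changes of -2.27, -2.06 and -1.86. Of 4 lymphoid genes tested 3 were lower and 1, Lck (1.82), was higher (median -3.01, camera adjusted p = 0.0359, but adjusted p = 0.142 with an estimated correlation and 0.0628 without fresh replicate 2). Ighm, the mu heavy chain gene, fell from 58.5 ± 2.38 to 2.18 ± 0.538 CPM. Of 3 eosinophil genes, 2 were called lower and the list was not called (camera adjusted p = 0.079, median -5.10, or -5.36 with genes at their bounds). Prg2 counted 104, 31 and 26 in fresh replicates 1 to 3, Epx counted 62, 10 and 4, and both were at 0 in expanded CMP, at least 86.9-fold and 41.0-fold lower. These bounds were 45.3-fold and 11.1-fold without fresh replicate 1, where Epx was too rare to be tested, and 50.9-fold and 24.03-fold without expanded replicate 1. Neither passed with a robust prior. Of 5 stromal and endothelial genes 3 were lower and 2 higher (camera adjusted p = 0.393), led by Col1a2 at -2.90, with Tek at -1.05, Kdr at 0.76 and Pdgfrb at 0.26, whose call was lost with libraries scaled to ribosomal protein genes (1 higher and 3 lower).

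Of 18 erythroid genes 14 were lower and 3 higher (median -1.72, camera adjusted p = 2.75e-06, 0.0273 with an estimated correlation). Car1, a carbonic anhydrase of early red cells, fell from 145 ± 5.55 to 5.14 ± 0.640 CPM, Ermap from 66.0 ± 1.46 to 2.59 ± 0.628 CPM, and the transcription factor gene Gata1 from 76.5 ± 7.31 to 21.7 ± 1.29 CPM. The 3 that rose were Hbb-bt (2.09), Hemgn (1.27) and Tal1 (0.12). The Tal1 call was lost with ribosomal protein scaling, library totals alone, limma, DESeq2, a mean count of at least 50 and each replicate left out but expanded replicate 2. Hbb-bs and Hbb-bt, adult beta globin genes that share most of their sequence, went in opposite directions (-4.40, or -5.04 without expanded replicate 2, and 2.09) and are uncertain, as is Hba-a2. Of 20 haem synthesis and iron genes 15 were lower and Ftl1 (0.40) and Fth1 (0.15), the ferritin subunits, were higher (median -0.47, camera adjusted p = 0.00121, but adjusted p = 0.0665 with an estimated correlation). The Fth1 call was lost with ribosomal protein scaling. Slc40a1, the iron exporter, had a log2 fold change of -2.93, Alas1 -1.76, Abcb10 -1.30 and Hfe -1.19.

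Of 13 mast cell and basophil genes 8 were lower and 3 higher (median -1.02, camera adjusted p = 0.00424, but adjusted p = 0.0715 with an estimated correlation). The members moved apart: Ms4a2, the beta chain of the IgE receptor, and Hdc, which makes histamine, had log2 fold changes of -4.68 and -4.52, while Fcer1a, the alpha chain of the IgE receptor, rose from 0.957 ± 0.121 to 11.1 ± 2.23 CPM and Gzmb, a granzyme, from 3.38 ± 0.960 to 128 ± 7.40 CPM. The other member that rose was Mcpt8 (1.77). Of 20 megakaryocyte and platelet genes 11 were higher and 5 lower, and the list was not called (median 0.24, camera adjusted p = 0.0571, or 0.0482 without fresh replicate 1). Ppbp and Thbs1 rose by 4.25 and 2.26. The 5 lower members were Slc35d3, Gp1bb, Vwf, Treml1 and Fli1 (-2.52, -2.47, -1.27, -0.55 and -0.21). The Treml1 call was lost with no filter, the replicate block, DESeq2, limma and each replicate left out but fresh replicate 1. Of 17 haematopoietic stem cell genes 8 were higher and 6 lower, and the list was not called (median 0.34, camera adjusted p = 0.0738). Fgd5 rose from 3.22 ± 0.579 to 34.1 ± 3.23 CPM, Mecom by 1.71 on the log2 scale, Mycn from 110 ± 2.33 to 319 ± 17.4 CPM, and Mpl, the thrombopoietin receptor, from 38.3 ± 3.44 to 106 ± 2.71 CPM. These had the largest changes among the list's called members. The higher call of Procr (1.27) was lost without fresh replicate 1. Among the lower members, Pdzk1ip1 (-0.49) lost its call with no filter, DESeq2, limma, thinning and other settings.

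Among genes whose proteins commonly define progenitor gates, Kit, the stem cell factor receptor, fell from 661 ± 12.2 to 366 ± 8.75 CPM (log2 fold change -0.85 ± 0.034 SE, edgeR adjusted p = 1.39e-27). Cd34 was at 212 ± 11.8 and 247 ± 3.81 CPM (0.22 ± 0.044 SE, edgeR adjusted p = 4.17e-05, and not called with libraries scaled to ribosomal protein genes). Fcgr3 did not pass, at 5.83 ± 0.629 and 5.75 ± 0.178 CPM, and Fcgr2b had a log2 fold change of -0.43 whose call was lost without fresh replicate 3, without expanded replicate 1 and with DESeq2. Cd48 (0.15) and Slamf1 (0.27) did not pass, though Slamf1 passed without fresh replicate 2 and Cd48 with thinned libraries. Ly6a had 7 fresh and 19 expanded counts and was not tested. Of the lineage factors, Gata2 fell from 663 ± 30.7 to 327 ± 10.7 CPM and Cebpa fell by 0.56 on the log2 scale, while Spi1 was at 75.4 ± 2.40 and 77.2 ± 3.65 CPM and did not pass. Of 23 cytokine receptor genes 12 were lower (13 adjusted over the list alone) and 7 higher (median -0.45, camera adjusted p = 0.00797, but adjusted p = 0.073 with an estimated correlation; 14 lower and 5 higher with libraries scaled to ribosomal protein genes), with Ifngr1 at -2.28 and Il6st at -1.77. Of 21 homing and adhesion genes 9 were lower and 7 higher (camera adjusted p = 0.288; 11 lower and 5 higher with libraries scaled to ribosomal protein genes), with the chemokine receptor genes Ccr2 and Cxcr2 at -4.86 and -1.57, L-selectin (Sell) at -2.35 and S1pr1 at -1.59. Of 4 Hox genes tested Hoxa10, Hoxa9 and Hoxa7 were lower (-1.39, -1.30 and -1.26) and none was higher. The list missed the threshold (camera adjusted p = 0.0552) and passed it without fresh replicate 3 (0.0471) or expanded replicate 3 (0.0405).

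**Figure D2:**
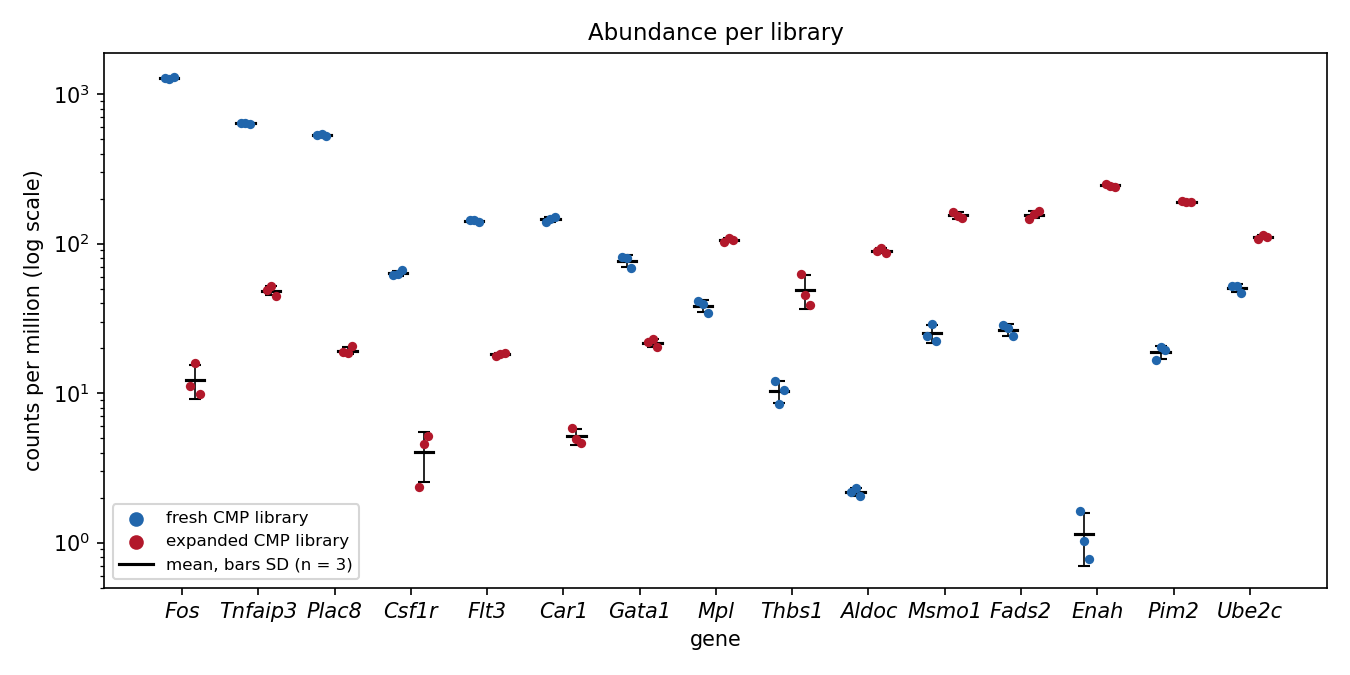
Abundance of 15 named genes in each library, in CPM on a log axis. Points are libraries (blue fresh, red expanded CMP), horizontal bars are means and error bars SD, n = 3 per group. The libraries of the groups do not overlap for any of these genes, and Fos lies at 1279 ± 13.02 CPM in fresh and 12.3 ± 3.21 CPM in expanded CMP.

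Of 25 genes of cholesterol synthesis and uptake 24 were higher and none lower (median 1.81, camera adjusted p = 5.7e-20, 0.00734 with an estimated correlation). Msmo1, a sterol demethylase, rose from 25.1 ± 3.45 to 155 ± 7.88 CPM (log2 fold change 2.62 ± 0.094 SE, edgeR adjusted p = 1.06e-32), and Mvd, Tm7sf2 and Pcsk9 had log2 fold changes of 3.12, 2.54 and 3.92. Of 15 genes of fatty acid synthesis and desaturation 13 were higher and none lower (12 and 1 with libraries scaled to ribosomal protein genes; median 0.88, camera adjusted p = 1.96e-10, 0.0247 with an estimated correlation). Besides Scd1, the desaturase genes Fads2 and Fads1 rose from 26.5 ± 2.29 to 156 ± 8.93 CPM and from 49.6 ± 1.90 to 208 ± 6.93 CPM. Me1, the malic enzyme gene, had 3 fresh counts and a CPM ratio of expanded to fresh of 43.9 (14.8 to 214).

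Of 24 glycolysis genes 19 were higher and 2 lower (19 and 4 with libraries scaled to ribosomal protein genes; median 1.21, camera adjusted p = 2e-12, 0.0122 with an estimated correlation). Aldoc, an aldolase, rose from 2.18 ± 0.126 to 89.6 ± 3.26 CPM and the lactate exporter Slc16a3 from 6.72 ± 1.94 to 32.1 ± 1.40 CPM. Bnip3, in the list though not an enzyme of glycolysis, rose from 13.4 ± 2.06 to 84.5 ± 4.72 CPM. The lower members were the hexokinase genes Hk3, which fell from 88.1 ± 1.93 to 21.5 ± 3.24 CPM, and Hk1 (-0.74). Of 24 unfolded protein and amino acid response genes 19 were higher and 4 lower (median 1.23, camera adjusted p = 2.51e-09, but adjusted p = 0.0715 with an estimated correlation). The members with the largest rises act in amino acid supply and its stress response. Besides Trib3, the cystine transporter gene Slc7a11 rose from 0.861 ± 0.526 to 69.4 ± 3.20 CPM, the glutathione-degrading Chac1 from 0.348 ± 0.144 to 35.3 ± 1.68 CPM, and Slc7a3 was at least 18.1-fold higher (11.95-fold without fresh replicate 2 and 11.97-fold without fresh replicate 3). The 4 lower members, Hspa5, Dnajb9, Sdf2l1 and Pdia4 (-1.22, -1.16, -1.11 and -0.23), are chaperones or cochaperones of the endoplasmic reticulum. Xbp1 and Herpud1, genes of the unfolded protein response, were among the 19 higher members. Of 20 antioxidant and metallothionein genes 9 were higher and 5 lower (camera adjusted p = 0.0923; 7 higher and 6 lower with libraries scaled to ribosomal protein genes). Srxn1, Mt2 and Mt1 had log2 fold changes of 2.16, 1.94 and 1.27, and the lower members were Hmox1, Gpx1, Sod2, Gclc and Prdx6 (-0.82, -0.38, -0.21, -0.20 and -0.16). The Sod2 call was lost without fresh replicate 2, that of Prdx6 without expanded replicate 1, and that of Gclc without fresh replicate 1, fresh replicate 2 or expanded replicate 1, with no filter, with DESeq2 and with thinning.

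All 26 mitosis genes were higher (median 0.72, camera adjusted p = 7.59e-15, 0.0247 with an estimated correlation), and all 26 stayed called with each scaling tried. Ube2c, which drives exit from mitosis, rose from 50.4 ± 2.88 to 111 ± 3.92 CPM, and Plk1, Hmmr and Cdc20 had log2 fold changes of 0.98, 0.93 and 0.91. The 27 DNA replication and S phase genes had 8 higher (9 adjusted over the list alone) and 11 lower (median -0.048, camera adjusted p = 0.379), or 3 higher and 14 lower with libraries scaled to ribosomal protein genes (median -0.191), with Tk1 and Rrm2 at 0.61 and 0.41 against Ung and Fen1 at -0.68 and -0.43. The Fen1 call was lost without fresh replicate 2, without fresh replicate 3, with DESeq2 and with thinning. Of 24 histone genes 22 were higher and none lower (median 0.51, camera adjusted p = 7.32e-13, but adjusted p = 0.0978 with an estimated correlation), with H1f0, Hist2h4, Hist1h4d and Hist1h3d at 1.62, 1.52, 1.21 and 1.11. Histone genes share long stretches of sequence, and the split of reads between them is uncertain.

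Of 46 ribosomal protein genes 35 were higher and 2, Rps24 and Rps9 (-0.097 and -0.090), lower, by small amounts (median 0.13, camera adjusted p = 8.98e-06, but adjusted p = 0.0715 with an estimated correlation). The list's call was lost with GC and length offsets (adjusted p = 0.517), and its median was -0.012 with libraries scaled to these genes. That scaling gave 13 higher and 11 lower members, and the offsets gave 24 higher and 7 lower. The Rps24 and Rps9 calls were lost with no filter, and that of Rps9 also without expanded replicate 3. The largest change was that of Rplp1, from 1310 ± 62.0 to 1665 ± 123 CPM, with Rpl14, Rps8 and Rpl6 at 0.33, 0.33 and 0.32. Of 13 mitochondrially encoded genes 9 were higher and none lower (median 0.31, camera adjusted p = 0.00153, but adjusted p = 0.278 with an estimated correlation and 0.847 with GC and length offsets). With ribosomal protein scaling 5 were higher and 2 lower, and with the offsets 6 higher and 3 lower. The rises were led by mt-Nd6, mt-Nd2, mt-Co2 and mt-Nd5 at 0.60, 0.57, 0.44 and 0.43. The share of counts from mitochondrial messenger RNA was 0.773% to 0.819% in fresh and 0.943% to 0.987% in expanded libraries. The mt-Co2 call was lost without fresh replicate 3 and with ribosomal protein scaling, DESeq2 and the offsets, and mt-Nd5 and mt-Nd6 overlap on opposite strands. Of 37 nuclear genes of the respiratory chain 15 were higher and 6 lower (median 0.090, or -0.054 with libraries scaled to ribosomal protein genes, camera adjusted p = 0.228). That scaling gave 2 higher and 12 lower members, and the GC and length offsets gave 9 higher and 7 lower. Cycs and Ndufa1 were at -0.82 and -0.51, and Ndufab1 and Ndufs7 at 0.49 and 0.36.

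Of 27 type I interferon response genes 16 were higher and 3, Zbp1, Oasl1 and Irf9 (-0.92, -0.67 and -0.34), lower (median 0.58, camera adjusted p = 0.00132, but adjusted p = 0.0672 with an estimated correlation). The Oasl1 call was lost without fresh replicate 2 and with DESeq2, and that of Zbp1 with thinning. Ifit1 rose from 4.70 ± 0.549 to 21.4 ± 0.903 CPM, and Rsad2, Ifit3 and Usp18 had log2 fold changes of 1.94, 1.94 and 1.93. Of 21 STAT5 and cytokine feedback genes 11 were higher (12 adjusted over the list alone) and 9 lower (median 0.37, camera adjusted p = 0.406). The largest changes were rises in Id1, from 3.14 ± 0.282 to 59.8 ± 4.12 CPM, Socs2, from 4.36 ± 1.17 to 67.7 ± 2.39 CPM, the kinase gene Pim2, from 18.7 ± 1.89 to 191 ± 2.41 CPM, and Bcl2l1, which encodes an inhibitor of apoptosis, from 29.9 ± 2.93 to 137 ± 4.68 CPM. Of 18 p53 target genes 5 were higher and 5 lower (median 0.25, mean -0.026, camera adjusted p = 0.766; 3 higher and 6 lower with libraries scaled to ribosomal protein genes). Bbc3 was at 1.22, and Plk2, Pmaip1 and Dcxr were at -2.61, -1.12 and -0.98. Xist was at 0 in all 6 libraries, and of 4 Y-linked genes 2, Kdm5d (0.25) and Uty (0.22), were called higher (camera adjusted p = 0.36). Both calls were lost with libraries scaled to ribosomal protein genes, and that of Uty also without fresh replicate 1, fresh replicate 2 or expanded replicate 3 and with DESeq2 and the offsets.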

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

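DESeq2, limma, totals alone, thinning, the GC and length offsets and the removal of Lars2, Gm26917 and Rn18s-rs5 were chosen after seeing the data. The count of changed genes, 6128, stayed between 4851 (DESeq2) and 6561 (ribosomal protein scaling) over 21 alternatives, and 4570 of the 6128 kept their call and direction in all 6 fits that left out a replicate. Leaving out a replicate gave 5593 to 5751 changed genes. Same-numbered replicates deviated together with correlations of 0.007, -0.02 and 0.008, which show no sign of pairing. The highest correlations with another number were 0.002, 0.02 and 0.018. With so small a spread between replicates, these values cannot exclude that the numbers pair the samples. With the replicate block 6145 genes were called. Of 2921 values of named genes under alternatives, 2897 kept their direction and side of the threshold, 24 crossed it and 0 reversed. The robust prior gives no list test.

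Ribosomal protein scaling called 1972 genes higher, since it moves every library by the rise of those genes. With a mean count of at least 50, 432 genes were at least 2-fold higher and 339 lower, and with no filter 1003 were at least 2-fold lower, fewer or more genes being tested. With an estimated correlation 8 lists were called, and the adjusted p became 0.0672 for late neutrophil and for interferon genes, 0.0945 for dendritic cell, 0.0715 for mast cell, ribosomal protein and unfolded protein and amino acid response, 0.142 for lymphoid, 0.278 for mitochondrially encoded, 0.0665 for haem, 0.073 for cytokine receptor and 0.0978 for histone genes. With no filter, stem cell (0.013), megakaryocyte (0.00966), eosinophil (0.00336), inflammatory (0.0342) and antioxidant lists (0.0152) passed. With a mean count of at least 50, late neutrophil (0.936), dendritic cell (0.0895) and lymphoid lists (0.0895) lost their calls. With ribosomal protein scaling stem cell (0.0225) and megakaryocyte lists (0.0327) passed, and ribosomal protein (0.157) and lymphoid lists (0.111) did not. The lymphoid call was also lost with a prior count of 0.1 (0.0623) and no abundance trend (0.0815). The GC and length offsets ended the calls of ribosomal protein (0.517) and mitochondrially encoded genes (0.847), and with thinning the inflammatory list passed (0.0306). The cause was not tested where none is given. Leaving out a replicate gave 0.0482 (without fresh replicate 1) to 0.0825 for the megakaryocyte list, 0.0201 to 0.0628 (without fresh replicate 2) for the lymphoid list and 0.0405 (without expanded replicate 3) to 0.0736 for the Hox list, which also passed without fresh replicate 3 (0.0471). The lowest correlation within a group, 0.987, became 0.98 and 0.992 with prior counts of 0.1 and 10, 0.983 with no filter and 0.992 with a mean count of at least 50. Over all alternatives with a list test, the adjusted p ran from 0.013 to 0.174 for stem cell, 1.8e-07 to 0.936 for late neutrophil, 5.25e-04 to 0.0945 for dendritic cell, 0.00966 to 0.433 for megakaryocyte, 1.46e-05 to 0.0715 for mast cell and 0.00336 to 0.302 for eosinophil genes. It ran from 0.00336 to 0.142 for lymphoid, 5.82e-10 to 0.517 for ribosomal protein, 2.1e-05 to 0.847 for mitochondrially encoded, 5.25e-05 to 0.0672 for interferon, 0.0306 to 0.407 for inflammatory and 2.15e-17 to 0.0715 for unfolded protein and amino acid response genes. The range was 0.0152 to 0.341 for antioxidant, 7.53e-06 to 0.0665 for haem, 3.01e-04 to 0.073 for cytokine receptor, 0.0405 to 0.443 for Hox and 1.15e-21 to 0.0978 for histone genes. Depth limits genes near the floor of 3 counts, and 5593 genes were called in thinned libraries.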

Other observations

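The lists of cytoskeleton, aminoacyl-tRNA synthetase, other amino acid response, chaperone, fetal and hypoxia genes were chosen after the values were seen. Their p-values come from the same data that prompted the lists and are not independent support. The tests of other splits, of carried-over neutrophils and monocytes, of marrow isolation and of the culture medium were chosen only after the result was seen.

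Genes of the actin and myosin cytoskeleton, which shape and move the cell, were higher in expanded CMP as a group: 27 of 33 tested members rose and none fell (27 higher and 1 lower adjusted over the list alone, median log2 fold change 0.54, limma camera adjusted p = 3.6e-14 over the lists chosen here, and adjusted p = 0.0243 with an estimated correlation). With libraries scaled to ribosomal protein genes Myl12a, Tpm3 and Arpc2 lost their calls. That scaling also called Myl12b, Actr2, Arpc3 and Tagln2 lower (-0.302, -0.168, -0.157 and -0.116). The non-muscle myosin heavy chain gene Myh10 rose from 50.5 CPM to 341 CPM, and Myh9 from 2526 to 5503 CPM. Flnb and Actn1, which link actin filaments, had log2 fold changes of 1.71 and 1.32, and Actb, an abundant actin gene, one of 0.61. These genes were picked for mention after their values were seen. The list also holds Enah (7.52), already among the largest rises.

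The real grouping called 6128 genes with edgeR, and 1 of the 10 splits of the 6 libraries into 3 and 3, the real grouping itself, gave as many. The highest of the other splits called 0 genes (58 to 86 genes at an unadjusted p under 0.05 with edgeR; DESeq2 was not run on them). With 10 splits no share under 0.05 can be had.

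All 22 immediate early genes were lower in expanded CMP. The tables argue against depth, since 22 of 22 stayed called lower in thinned libraries (median log2 fold change -3.66 before and -3.67 after), and against a GC or length bias, since 22 of 22 stayed called with those offsets (-3.65). For Fos, neutrophils carried into the fresh sort are argued against too, as S100a8 and S100a9 together reached 3.12% of its CPM in fresh CMP. That share does not cover rarer members such as Hspa1b, at 56.77 CPM in fresh CMP against 26.0 CPM for S100a9. The handling of marrow before lysis, which may induce these genes, stays open along with a difference between marrow and culture, because 0 libraries separate isolation from culture.

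Among primary granule and monocyte genes 26 were called lower in expanded CMP. Depth and base content do not account for this, since 25 of 26 stayed called in thinned libraries (median -4.08 before and -4.09 after) and 26 of 26 with the GC and length offsets. Mature neutrophils in the fresh sort are argued against as the source of most primary granule RNA: 6 mature neutrophil genes, 5 of them tested, summed to 2.31% of the CPM of 4 primary granule genes. Mpo made up most of the latter sum (3015 of 3536 CPM). The share does not decide the rarer Prtn3, Ctsg and Elane (237, 181.3 and 102.5 CPM, against 81.83 CPM for the 6 genes). Mature monocytes and macrophages stay open for the monocyte genes. A set of 7 genes abundant in them lost 9.58 CPM, 1.91% of the 502 CPM lost by 7 genes expressed from monocyte progenitors on, but mature monocytes express those genes too, and 1 of the first 7 was tested (Lyz2, at 59.2 and 52.4 CPM, whose call was lost with 5 of 6 replicates left out, all but fresh replicate 1). Of the rare ones, C1qa (13 to 0 counts), C1qb (8 to 1), C1qc (12 to 0) and Cd14 (24 to 3) nearly vanished, as they would with a trace of macrophages in the fresh sort. Fcgr1 (5 to 38 counts, 0.433 to 2.045 CPM) and Lyz1 (1 to 8 counts, 0.0855 to 0.456 CPM) went the other way. None of these was tested. Fewer cells set on granulocyte and monocyte fates among the expanded cells, which bulk libraries cannot separate from lower expression in each cell, stay open too and were not tested.

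Among cholesterol and fatty acid genes 37 were called higher in expanded CMP. Of these, 36 of 37 stayed called in thinned libraries (median 1.71 before and 1.74 after), and 36 of 37 with the GC and length offsets (1.70), which argues against depth and base content. The serum-free medium may bring little lipid, but 0 libraries came from another medium, so that the medium, the 7 days of culture and the stem cell origin of the cells cannot be told apart.

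In the list of unfolded protein and amino acid response genes, whose call was lost with an estimated correlation (adjusted p = 0.0715), 19 members rose and 4 chaperones or cochaperones of the endoplasmic reticulum fell. The 19 include Xbp1 and Herpud1, genes of the unfolded protein response, and Hsp90b1 was not called. An amino acid response may take part. On further lists, 16 of 20 aminoacyl-tRNA synthetase genes were higher and none lower (median 0.82, limma camera adjusted p = 1.71e-11). With libraries scaled to ribosomal protein genes Dars, Farsb and Kars lost their calls, and Farsa, Hars and Rars were called lower (-0.179, -0.161 and -0.16). Of 21 other amino acid response genes 19 were higher (20 adjusted over the list alone) and 1, Shmt1, lower (median 1.68, limma camera adjusted p = 1.25e-13). The Shmt1 call was lost without fresh replicate 2, expanded replicate 1 or expanded replicate 3, and with no filter, DESeq2 and thinning. Both list calls held with an estimated correlation (limma camera adjusted p = 0.00753 for each). Nars is in both lists. Of 21 further chaperone genes 6 were higher and 9 lower (median -0.016, limma camera adjusted p = 0.283). The higher ones were Ero1l (1.47), Sec61b (0.30), Sel1l (0.23), Edem1 (0.22), P4hb (0.15) and Canx (0.14), and the lower ones by Creld2 (-0.92) and Ero1lb (-0.77), with Pdia6 at -0.54, Hyou1 and Dnajb11 at -0.50 each, Calr at -0.40, Manf at -0.35, Dnajc3 at -0.29 and Pdia3 at -0.20. Sel1l, Edem1, P4hb and Canx lost their calls with libraries scaled to ribosomal protein genes, and Edem1 also without fresh replicate 2. The same scaling called Dnajc10 and Ssr1 lower (-0.16 and -0.09), while the GC and length offsets called Ssr1 higher (0.088). These further chaperones did not rise as a set, a result that the prediction written before had counted against an unfolded protein response. A response that raises only some of them stays open, since members were called both ways. The trigger was not tested.

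Glycolysis genes include many that hypoxia induces, and a hypoxia response may take part in their rise. Of 17 hypoxia-induced genes outside glycolysis 10 were higher (12 adjusted over the list alone) and 2 lower (median 0.33, limma camera adjusted p = 0.00133, and adjusted p = 0.031 with an estimated correlation). Vegfa and P4ha1 rose by 1.75 and 1.71, while Ndrg1 and Narf fell by 0.74 and 0.18 on the log2 scale. The Narf call was lost without fresh replicate 2 or expanded replicate 2 and with DESeq2. Ddit4, Stc2 and Ero1l also belong to the amino acid or chaperone lists. Bnip3 and Egln3 were counted in the glycolysis list and not in the hypoxia list. Oxygen during culture is not given in the sources used here.

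Lin28b, an RNA-binding protein of fetal blood stem cells, had 1 fresh count and rose to 4.23 CPM in expanded CMP. A wider fetal program stays open. Of 18 genes in a fetal and oncofetal list 6 were tested, Lin28b among them, and the other 5 went both ways: 1 of 5, Hmga1, was higher (2 adjusted over the list alone, with Dlk1 at 0.75, which was called higher without fresh replicate 2 or expanded replicate 3), and Igf2bp2, Hmga2 and Arid3a were lower (limma camera adjusted p = 0.811 for the list). With 6 genes tested and members called both ways, such a result decides nothing, although the prediction had counted it against a wider program.

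Scd1 and Trib3 had 4 counts each in fresh replicate 2 and 0 in fresh replicates 1 and 3, against 5234 and 2907 counts in the expanded libraries together.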
